A study of Homo sapiens with 12 samples.

How the data were processed

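Gene expression was measured on arrays with biotin-labelled total RNA from the Ewing sarcoma cell lines A673 and TC32. Each line was treated for 6 hours with the solvent DMSO or with THZ531 at 100 nM or 500 nM, which gave 6 groups of 2 arrays, called biological replicates in the labels. The labels of the DMSO samples also carry a dose of 100 nM, which was read as not applying to them. The deposited values are log2 signals, normalised by the authors by a method not given in the sources used here. The submitters' processing notes name MAS5 and the genome builds GRCh37 and hg19 without saying how they were used. External RNA controls (the ERCC mix) were added to total RNA, per the labels, and no probe set bearing their names was used here. Whether the authors scaled the arrays to those controls is not known, so an equal shift of all genes between arrays can be a difference in RNA amount per input or a difference in scaling.

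The table held 49395 probe sets and 12 columns. Of the probe sets, 44994 were annotated to 1 gene, 1832 to several genes and 2569 to none, and only the first were used. In 46566 entries the values had 3 decimals, and these repeated 1 gene-level value on the probe sets of a gene, which left 17936 distinct sets of values. Such a value does not tell which transcript of a gene gave the signal. The other 2829 entries (5.73%, 92 of them array controls) had at most 2 decimals, and their columns lay nearest to columns of other groups, so they were used in no comparison. That exclusion was decided after the table had been examined. Among 17007 genes with a 3-decimal entry, 92 were left out because another symbol had the same values, and 16915 were kept. Each gene was represented by its probe set with the highest mean, a choice that mattered for the 21 genes with more than 1 distinct set of values. Another 1103 genes had only 2-decimal entries and were not analysed here.

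Genes were tested when their mean log2 value over the 12 arrays was at or above the 40th percentile (5.95), which left 10149 genes. The comparisons, tests, filters, gene lists and the rule for naming genes were fixed before the data were examined. A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean signal, two-sided tests and Benjamini-Hochberg adjusted p under 0.05. Tables were prepared with Python 3.11.15 and pandas 2.3.3. The contrasts were each dose against DMSO and 500 nM against 100 nM in each line, the 500 nM effect averaged over both lines, the difference of each dose's effect between the lines (TC32 minus A673), and A673 against TC32 under DMSO. The main tests used the values as deposited. Every result was also computed relative to the array medians, that is, with each array centred on its median over all 16915 kept genes, and values called relative in the text come from it. Fitted log2 differences are printed also where a group mean lies under the filter level of 5.95, while folds of such genes are counted from that level and given as lower bounds. List members called lowest or most deeply fallen are so by fitted value, which is no ranking where a group mean lies under that level.

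The p-values measure the spread between these samples. On the values as deposited, the median residual SD was 0.208 with 6 residual degrees of freedom, and limma estimated an infinite prior degree of freedom, since offsets of whole arrays dominate that spread and are shared by all genes. The resulting adjusted p-values treat genes as independent and are smaller than 2 arrays per group can warrant. After centring, the median residual SD was 0.125 and the prior degrees of freedom were 15.76. The number of arrays limits the precision of every value. The model was tested on simulated data with 10149 genes, built from the DMSO levels with changes planted in the A673 500 nM comparison. It recovered 91 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2, with 10 false calls. The simulated noise was independent for each gene, without offsets of whole arrays, and only 200 genes changed. These false calls therefore do not measure those in the real comparison.

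Shifts of 24 gene lists were tested with camera in limma, which compares a list with all other genes, so that a list can test as higher while its members are lower than in DMSO. The preset correlation between genes was 0.01, p-values were adjusted over the lists, and the test was repeated with an estimated correlation. On the values as deposited, offsets of whole arrays are shared by all genes and can raise that estimate. A list not called with it is therefore not shown to be unshifted. Member counts are given over all tested genes and, where that differs, adjusted over the list alone. The lists covered the DNA damage response, EWS/FLI-activated and EWS/FLI-repressed genes, transcription factors of Ewing sarcoma, immediate-early transcripts, p53 targets, apoptosis, transcription elongation, splicing, 3' end processing, G1/S, G2/M, ribosome biogenesis, the unfolded protein and integrated stress responses, heat shock proteins, NF-kB and interferon, Wnt, TGF-beta and Hippo targets, haematopoietic, epithelial, endothelial and fibroblast, and neural markers, replication-dependent histones, cytoplasmic ribosomal proteins and oxidative phosphorylation subunits. Some genes stand in more than 1 list, 23 in all.

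Named genes were, for each line, the 10 largest rises and 10 largest falls at 500 nM and the 5 and 5 at 100 nM among genes past the threshold whose treated arrays both lay beyond both DMSO arrays. The rule also took up to 2 rises and 2 falls from each list at 500 nM, the 5 largest differences between lines in each direction, the 5 highest genes of each line under DMSO, and always CDK12, CDK13, CCNK, FLI1, EWSR1, MYC and BRCA1. Probe sets of several genes were skipped, and 1 further gene that the rule names is not reported here. The text names genes of that set unless it says otherwise. Genomic lengths came from a RefSeq table on a later build (GRCh38), used as a property of each gene, and correlations with length or between effects run across genes, which are not independent replicates. Alternatives covered the scaling, the brightness filter, the choice of probe set, the variance model, each line fitted alone, a replicate block, a fold threshold, leaving out each array, and the correlation in camera, with their effect given in the closing section.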

Results

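The series profiled gene expression in 2 Ewing sarcoma cell lines, A673 and TC32, to follow the effects of THZ531 on transcription. Ewing sarcoma is a bone and soft tissue tumour driven by a fusion of EWSR1 with an ETS gene, in these lines EWS/FLI, and THZ531 is a covalent inhibitor of CDK12 and CDK13, cyclin K-dependent kinases that phosphorylate RNA polymerase II during elongation. RNA was taken after 6 hours with DMSO, 100 nM or 500 nM THZ531, with 2 arrays in each of the 6 groups. Over the 10149 tested genes, the array medians were 8.87 and 8.79 (log2) in A673 with DMSO, 8.16 and 8.12 at 100 nM, and 7.98 and 7.43 at 500 nM. In TC32 they were 8.08 and 7.94 with DMSO, 7.72 and 7.72 at 100 nM, and 6.87 and 6.89 at 500 nM. Replicates correlated across genes between 0.9906 and 0.9968, and the A673 replicates at 500 nM were offset from each other by a median of 0.52, the largest offset of any pair.

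**Figure D1:**
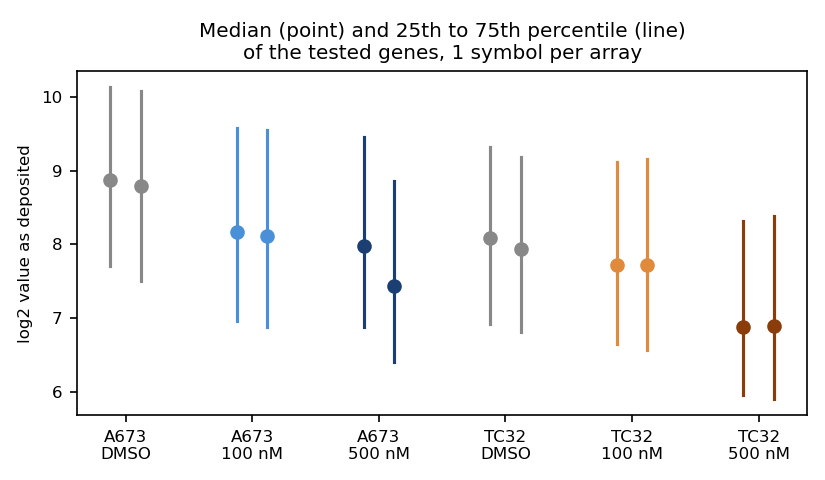
Median (point) and 25th to 75th percentile (line) of the deposited log2 values of the 10149 tested genes on each of the 12 arrays, by group. Medians ran from 8.87 in A673 with DMSO to 6.87 in TC32 at 500 nM, and the A673 replicates at 500 nM lay at 7.98 and 7.43.

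In A673 cells at 500 nM THZ531, most measured transcripts were below DMSO as deposited, and a small set above it included small nucleolar RNAs, histones and immediate-early genes. The largest fitted fall was that of ZC3H4, a zinc finger protein that restrains noncoding transcription, at -4.48 ± 0.21 (log2, SE, n = 2 against 2), at least 20.3-fold lower as deposited and -3.65 relative to the array medians. The largest fitted rise was that of the small nucleolar RNA SNORA65, at 3.44 ± 0.21, at least 7.97-fold higher as deposited and 4.28 relative to the array medians. By limma, 8378 genes were lower and 96 higher as deposited, with a median change of -0.73, and 3385 and 44 of these changed by at least 2-fold. Centring the arrays took a shift of -0.835 out of this comparison. Relative to the array medians 3036 genes (52.2%) were higher and 2775 lower, against 1.1% higher as deposited. The count of higher genes was 163 without replicate 2 of the 500 nM arrays, and the median change was -0.47 without it.

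Of the 10 lowest fitted values named in A673, only that of ARID2, a chromatin remodelling subunit gene, came from group means both above the brightness minimum of 5.95 (-3.76, from 10.54 to 6.78). The others, like ZC3H4, had a 500 nM mean under that level, so their order is not a ranking of the falls. They were those of the ubiquitin ligase genes RNF111 (-3.98) and TRIM32 (-3.78), the PI3-kinase regulatory subunit gene PIK3R1 (-3.91), the zinc finger gene ZNF827 (-3.89) and the cell cycle repressor gene E2F8 (-3.85). CSPP1 (-3.84) and CEP350 (-3.77), both genes of centrosome proteins, and IRS1 (-3.77), an adaptor of insulin signalling, were the rest. Relative to the array medians these values after ZC3H4 were between -3.14 for RNF111 and -2.93 for ARID2. The rises with both means above it were those of the polyamine enzyme gene SAT1 (2.60), the small nucleolar RNA SNORA84 (2.44), the histone gene H2AC8 (2.28), the activity-regulated gene ARC (1.99), the small nucleolar RNA host gene SNHG17 (1.92) and IER3 (1.83). The small nucleolar RNAs SNORD12B (2.65) and SNORA74A (2.22) and EID3 (1.95), like SNORA65, started under it with DMSO. Of the 84 genes named for this comparison, 80 passed the test, and for 79 of them both 500 nM arrays lay beyond both DMSO arrays, SYP being the exception. For the 10 largest rises and 10 largest falls the naming rule required this. For 20 of the 84 a group mean lay under 5.95.

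The kinases that THZ531 targets were lower in A673 at 500 nM, CDK13 at -2.65 (relative -1.82) and CDK12 at -1.48 (relative -0.64). At that dose the CDK13 mean lay under 5.95. Their partner cyclin K, encoded by CCNK, was at -0.91 as deposited (adjusted p 2.87e-05) and -0.08 relative to the array medians (adjusted p 0.551). FLI1, the ETS gene whose 3' part the fusion carries, fell by 2.66 (relative -1.83). EWSR1 was at -0.46 as deposited (adjusted p 0.0207) and at 0.38 relative to the array medians, so its direction turns with the scaling. The as-deposited call for EWSR1 ended without replicate 1 or replicate 2 of the DMSO arrays (adjusted p 0.142 and 0.0522) or replicate 2 of the 500 nM arrays (-0.16, adjusted p 0.185). MYC, a short-lived transcription factor transcript, was at 0.14 (adjusted p 0.442) and 0.97 relative.

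Genes of mitosis and of the DNA damage response tested as falling further than other genes in A673 with the preset correlation. With an estimated one, which array offsets can raise, neither list was called. All 28 tested genes of G2/M and mitosis fell as deposited (camera adjusted p 3.01e-05; adjusted p = 0.943 with an estimated correlation), among them the kinetochore genes NDC80 (-3.53) and CENPA (-3.27), and 19 were lower and 1 higher relative to the array medians. In the DNA damage response list 31 of 33 fell (adjusted p 0.00219; adjusted p = 0.943 with an estimated correlation), with PALB2, a homologous recombination scaffold, at -3.50, the helicase gene BLM at -2.78 and BRCA1, a homologous recombination gene, at -1.45, and 20 were lower and 3 higher in relative terms. Of 29 G1/S and DNA replication genes all fell, led by the replication licensing genes CDC6 (-2.42) and MCM10 (-1.79), yet the list did not fall further than other genes (camera adjusted p 0.626), and 8 were higher and 9 lower in relative terms.

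Replication-dependent histones and immediate-early transcripts moved the other way. Among 26 histone genes 14 rose and 7 fell as deposited (camera adjusted p 1.09e-18; adjusted p = 0.815 with an estimated correlation), and the risers H2AC8 (2.28) and H2BC8 (1.60) encode core histones. Without replicate 2 of the 500 nM arrays 3 histone genes fell, and without replicate 1 of the DMSO arrays 2 fell, while without either 100 nM array 4 did. Of 35 immediate-early and short-lived transcripts 16 rose and 10 fell (adjusted p 1.09e-18; adjusted p = 0.815 with an estimated correlation), with FOS, a subunit of AP-1, at 1.76 and the C/EBP family gene CEBPB at -1.79. Without replicate 1 of the 500 nM arrays 16 fell. Relative to the array medians 26 of these 35 were higher and 3 lower.

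The 3 lists related to EWS/FLI had medians below DMSO in A673 as deposited, at -0.86 for activated genes, -0.38 for repressed genes and -0.98 for transcription factors, while relative to the array medians they were at -0.02, 0.45 and -0.15. In the EWS/FLI-activated list 27 of 33 genes fell, BCL11B (-3.61), a zinc finger transcription factor gene, and the cell cycle gene E2F3 (-3.26) most deeply, but the list did not differ from other genes (camera adjusted p 0.717), and in relative terms 13 were higher and 7 lower. The EWS/FLI-repressed list lay above other genes (adjusted p 8.42e-06; adjusted p = 0.943 with an estimated correlation), with a mean of -0.12 and 4 of 18 risen, IER3 (1.83) and the matricellular gene CCN1 (1.18) among them, and 7 fallen (6 adjusted over the list alone). Without replicate 1 of the 500 nM arrays 14 of its genes fell, and without replicate 2, or without replicate 1 of the DMSO arrays, 4 did. Of 20 transcription factors of Ewing sarcoma 16 fell, such as the homeobox gene MEIS1 (-3.25), and 1 rose, the helix-loop-helix inhibitor gene ID1 (1.03), with camera adjusted p 0.157.

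Machinery of RNA synthesis and processing mostly fell in A673 as deposited, without a shift beyond other genes. In the transcription elongation list 27 of 31 fell (28 adjusted over the list alone; camera adjusted p 0.160), with MEPCE, the 7SK capping enzyme gene, at -2.51, and 15 were lower and 5 higher in relative terms. In the 3' end processing list 19 of 25 fell (adjusted p 0.125), SCAF4 (-3.12) and the poly(A) polymerase gene PAPOLG (-3.07) most deeply, with 8 higher and 10 lower in relative terms. PAPOLG had a 500 nM mean under 5.95. Splicing factors and CLK kinases fell in 30 of 33 cases (adjusted p 0.717), or 18 without replicate 1 of the DMSO arrays, including RBM5 (-2.74) and CLK2 (-1.96), with 16 higher and 7 lower in relative terms. In the ribosome biogenesis list 24 of 29 fell (adjusted p 0.634), led by PPAN (-2.49) and the polymerase I subunit gene POLR1B (-2.42), while in relative terms 9 were higher and 10 lower.

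Stress and signalling lists in A673 also held mainly falls as deposited. Among 24 p53 targets 19 fell and 2 rose (camera adjusted p 0.574), the phosphatase gene PPM1D at -2.05 and the polymerase gene POLH at -2.03 against the kinase gene PLK2 at 1.22 and GADD45A, a growth arrest gene, at 0.75. Apoptosis regulators fell in 17 of 20 cases (adjusted p 0.944), or 11 without replicate 1 of the DMSO arrays, with the survival genes BCL2 (-2.14) and XIAP (-1.85) lowest. The 500 nM means of BCL2 and POLH lay under 5.95. In the unfolded protein and integrated stress response list 18 of 22 fell (adjusted p 0.563), with XBP1 (-2.76), a transcription factor of that response, lowest. Heat shock proteins fell in 12 of 17 cases as deposited (adjusted p 0.123), or 7 without replicate 2 of the 500 nM arrays or replicate 1 of the DMSO arrays, while 11 were higher relative to the array medians. Of 14 NF-kB and interferon genes 8 fell (adjusted p 0.157), or 5 without replicate 2 of the 500 nM arrays, and of 12 Wnt, TGF-beta and Hippo targets 7 fell and 2 rose (adjusted p 0.157), among them LATS2 (-1.87), a Hippo kinase gene, and CCN2 (1.11). In relative terms the falls no longer prevailed except among p53 targets, of which 6 were higher and 12 lower. The higher and lower genes numbered 7 and 6 for apoptosis, 8 and 7 for the stress responses, 11 and 1 for heat shock, 5 and 4 for NF-kB and interferon, and 6 and 4 for Wnt, TGF-beta and Hippo targets.

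The direction of ribosomal protein and oxidative phosphorylation genes in A673 depends on the scaling. The cytoplasmic ribosomal proteins had a median of -0.29 as deposited, where 41 of 68 fell (27 adjusted over the list alone; camera adjusted p 3.72e-05; adjusted p = 0.943 with an estimated correlation). Relative to the array medians it was 0.54, and 65 rose (adjusted p 4.54e-20; 0.288 with an estimated correlation). Oxidative phosphorylation subunits had a median of -0.41 as deposited, where 46 of 69 fell (42 adjusted over the list alone; adjusted p 0.000137; adjusted p = 0.943 with an estimated correlation). After centring it was 0.43, and 62 rose (adjusted p 2.62e-10; 0.526 with an estimated correlation). Without replicate 1 of the 500 nM arrays 67 ribosomal protein genes fell and the oxidative phosphorylation call ended (adjusted p 0.499), without replicate 2 the falls were 5 and 17, and without replicate 1 of the DMSO arrays they were 6 and 12. Among markers of other cell types, 3 of 6 endothelial and fibroblast and 4 of 8 neural markers fell as deposited, or 1 and 0 without replicate 1 of the DMSO arrays, 5 and 7 without replicate 1 of the 500 nM arrays, and 0 neural ones without replicate 2. The receptor gene PDGFRB was at -0.85 (relative -0.02), and SNAP25 (-0.60), VWF (-0.60) and SYP (-0.55) fell as deposited but turn positive relative to the array medians (0.23, 0.24 and 0.29). Those 3 calls ended without replicate 1 of the DMSO arrays (adjusted p 0.0849, 0.129 and 0.36) or replicate 2 of the 500 nM arrays (0.124, 0.122 and 0.323). CD79A (-0.44, adjusted p 0.0473; relative 0.40) lost its call without any array but replicate 1 of the A673 500 nM arrays, with adjusted p between 0.0625 and 0.241. The globin gene HBB (-0.41, adjusted p 0.0718), the claudin gene CLDN4 (-0.37, adjusted p 0.0849) and the mucin gene MUC1 (-0.31, adjusted p 0.155) missed the test, and all 3 turn positive relative to the array medians. The camera adjusted p was 0.216 for haematopoietic markers, 0.0895 for epithelial markers, 0.157 for endothelial and fibroblast markers and 0.0534 for neural markers. Without either 500 nM array the epithelial and neural lists lay above other genes, and the neural list also did so without replicate 1 of the DMSO arrays. With all arrays and an estimated correlation, camera called 0 of the 24 lists in A673 at 500 nM. Given the offsets between arrays, that does not show the lists to be unshifted.

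**Figure D2:**
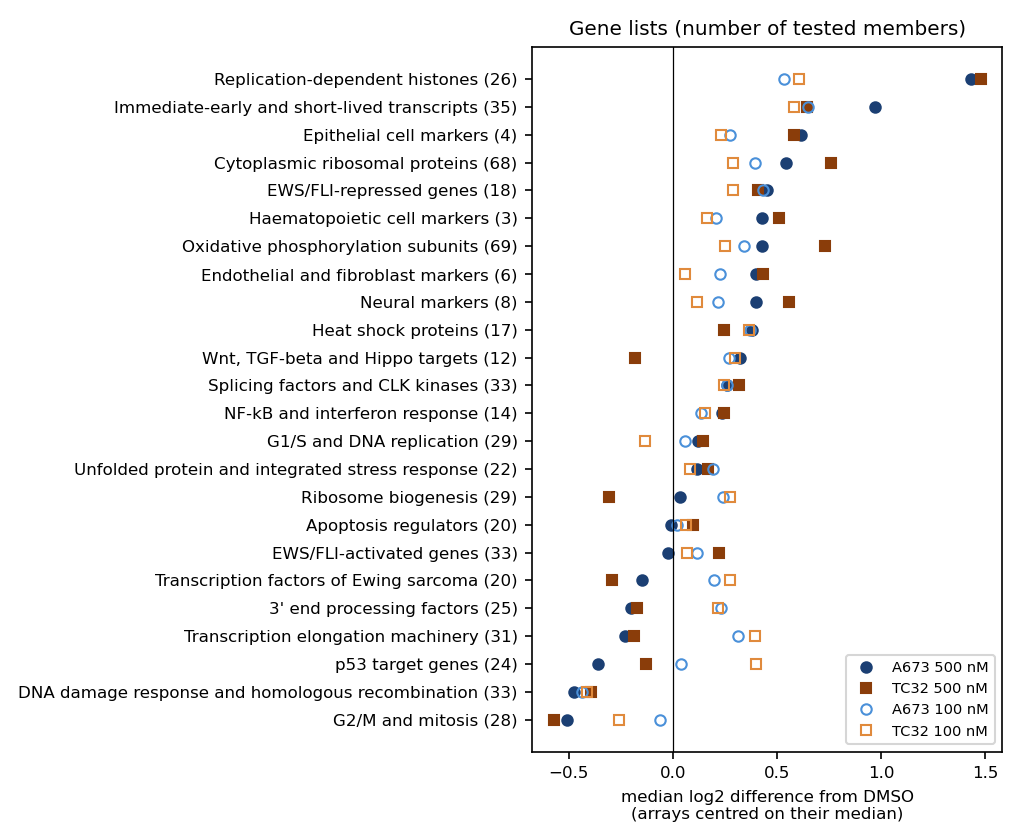
Median log2 difference from DMSO of each gene list, with arrays centred on their medians, for both doses in A673 and TC32 (filled symbols 500 nM, open symbols 100 nM; tested members in parentheses). Relative to the array medians the histones lay highest at 500 nM (1.43 in A673 and 1.48 in TC32) and G2/M genes lowest (-0.51 and -0.57), and as deposited only the histones in both lines and the immediate-early transcripts in A673 had medians above DMSO at 500 nM.

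In TC32 cells at 500 nM, ZC3H4 and SNORA65 again had the lowest and the highest fitted values of the changed genes, each with a group mean under 5.95. Of the genes with both group means above it, GDF6 (-4.21) and EGR1 (3.02) lay furthest from DMSO. ZC3H4 fell by 4.50 ± 0.21 (log2, SE, n = 2 against 2), at least 14.4-fold lower as deposited and -3.70 relative to the array medians, and SNORA65 rose by 3.60 ± 0.21, at least 6.39-fold as deposited and 4.39 in relative terms. The early growth response gene EGR1 (3.02) and IER3 (2.81) also rose, from DMSO means above 5.95. PLK2 (2.98), H2AC8 (2.92) and the histone gene H3C1 (2.67) started under it, and counted from it they rose by at least 1.76, 1.99 and 1.55. By limma 6386 genes were lower and 96 higher as deposited, with a median change of -0.64, and 3420 and 46 of these changed by at least 2-fold. Centring took a shift of -0.795 out of this comparison. Relative to the array medians 4198 genes (57.4%) were higher and 3112 lower, against 1.5% higher as deposited.

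Further deep falls in TC32 were those of the bone morphogenetic ligand gene GDF6 (-4.21), CENPA (-4.20) and BCL11B (-3.99), with both means above 5.95. E2F8 (-4.49), the zinc finger genes ZNF7 (-4.33) and ZBED5 (-4.28), the Golgi gene GORAB (-4.17), IRS1 (-3.94) and LRIF1 (-3.87) had a 500 nM mean under it. SAT1 (2.67) rose as it had in A673, and so did SNORA84 (2.57), SNORD12B (2.55) and SNORA74A (2.47), which started under 5.95. CDK13 fell by 2.05 (relative -1.25), CDK12 fell by 1.25 (relative -0.45) and FLI1 fell by 3.32 (relative -2.53), the 500 nM means of CDK13 and FLI1 lying under 5.95. CCNK was at -0.93 (relative -0.13) and EWSR1 at -0.42 as deposited (adjusted p 0.0434), a value that turns to 0.38 relative to the array medians. The EWSR1 call ended without any of 10 arrays in turn, with adjusted p 0.226 and 0.0947 without TC32 DMSO replicates 1 and 2, 0.157 and 0.144 without the 500 nM replicates, 0.0677 and 0.0678 without the 100 nM replicates, and 0.0633, 0.0631, 0.0725 and 0.0726 without the A673 arrays with DMSO and at 100 nM. MYC was at -0.57 as deposited (adjusted p 0.00221), a call that ended without replicate 1 of the 500 nM arrays (-0.43, adjusted p 0.102), and at 0.23 relative (adjusted p 0.072). Both 500 nM arrays lay beyond both DMSO arrays for all 72 of the 76 genes named for TC32 that passed the test, as the naming rule required of the 10 largest rises and 10 largest falls. For 30 of the 76 a group mean lay under 5.95.

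Mitosis and repair genes were again low in TC32 and histones high, while the G1/S list did not pass the list test. Among the genes named for these lists PALB2, BLM and CCNE2 had 500 nM means under 5.95. Of 28 G2/M genes 27 fell (camera adjusted p 5.11e-05; adjusted p = 0.914 with an estimated correlation), with NDC80 at -3.70, and 21 were lower and 3 higher in relative terms. In the DNA damage response list 30 of 33 fell (adjusted p 0.0493; adjusted p = 0.914 with an estimated correlation), and PALB2 (-3.42), BLM (-2.81) and BRCA1 (-1.13) were among them. Adjusted over the list alone, 30 fell and 1 rose. That call ended without replicate 1 of the TC32 DMSO arrays (adjusted p 0.0665) and without replicate 2 of the 500 nM arrays (0.0589). Of 29 G1/S genes 22 fell, or 12 without replicate 1 of the DMSO arrays, with the cyclin gene CCNE2 (-3.10) and the phosphatase gene CDC25A (-2.97) lowest (adjusted p 0.155). Among 26 histone genes 14 rose and 2 fell (adjusted p 1.79e-21; adjusted p = 0.914 with an estimated correlation), or 1 without replicate 1 of the DMSO arrays or either 500 nM array, and 24 were higher in relative terms.

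Immediate-early transcripts in TC32 rose in 10 of 35 cases and fell in 12 as deposited, with a median of -0.15 and a mean of 0.06 (camera adjusted p 5.56e-09; adjusted p = 0.914 with an estimated correlation). In relative terms 23 were higher and 4 lower (adjusted p 0.000165; adjusted p = 0.451 with an estimated correlation). CEBPB (-2.25) and the Kruppel-like factor gene KLF2 (-1.29) fell. The transcription factors of Ewing sarcoma lay below other genes (adjusted p 0.00468; adjusted p = 0.914 with an estimated correlation), with 15 of 20 fallen. That call ended after centring (adjusted p 0.0992) and without replicate 1 or replicate 2 of the A673 500 nM arrays (0.055 and 0.0548), which enter the shared fit. Ribosome biogenesis genes fell in 24 of 29 cases (25 adjusted over the list alone; adjusted p 0.0245; adjusted p = 0.914 with an estimated correlation), PPAN (-2.86) and POLR1B (-2.72) most deeply. This call ended after centring (0.0537) and without replicate 1 of the 500 nM arrays (0.0524). The EWS/FLI-repressed list lay above other genes (adjusted p 0.000689; adjusted p = 0.914 with an estimated correlation). IER3 rose (2.81, relative 3.60) and the forkhead gene FOXO1 fell (-1.11, relative -0.32), so how far its members moved depends on the scaling. EWS/FLI-activated genes fell in 19 of 33 cases without a shift of the list (adjusted p 0.647), and in relative terms 15 were higher and 11 lower.

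In the elongation list of TC32, 25 of 31 genes fell (camera adjusted p 0.167), MEPCE (-3.22) and the CDK-activating kinase gene CDK7 (-2.29) lowest. HEXIM1 (0.64), a gene of a P-TEFb inhibitor, and the bromodomain gene BRD2 (0.56) were above DMSO (adjusted p 0.00268 and 0.00701). Those calls ended without replicate 2 of the DMSO arrays (0.103 and 0.0815), that for HEXIM1 also without replicate 1 (0.0588) and that for BRD2 without replicate 2 (0.0621) of the 500 nM arrays. PAPOLG (-3.60) and the termination factor gene PCF11 (-2.94) were the lowest of the 3' end processing genes, of which 17 of 25 fell (adjusted p 0.0825). RBM5 (-2.90) and CLK2 (-2.26) were the lowest splicing genes, of which 20 of 33 fell (19 adjusted over the list alone; adjusted p 0.716). Of 24 p53 targets 17 fell, POLH (-2.26) and PPM1D (-2.06) lowest, and PLK2 and GADD45A (2.34) rose (adjusted p 0.612). XBP1 (-3.14) and HERPUD1 (-2.95), a gene of endoplasmic reticulum-associated degradation, fell with 15 of 22 stress response genes (adjusted p 0.271), as did the co-chaperone gene DNAJB1 (-2.10) with 10 of 17 heat shock genes (adjusted p 0.491). The apoptosis gene PMAIP1 (0.80) rose while BIRC2 (-1.93) and the caspase gene CASP8 (-1.68) fell with 13 of 20 apoptosis genes (adjusted p 0.797). The Hippo target list held 8 falls among 12 genes, AJUBA (-3.26) and TGIF1 (-2.23) lowest (adjusted p 0.296), and the chemokine gene CCL2 rose by 2.04 in the NF-kB list (adjusted p 0.0583). Like PAPOLG and PCF11, the genes POLH, PPM1D, XBP1, HERPUD1, CASP8 and AJUBA had 500 nM means under 5.95, so their order is not a ranking. In relative terms the balance turned for splicing (18 higher, 6 lower), the stress responses (10 and 8), heat shock (8 and 4) and NF-kB (6 and 2), and was even for apoptosis (8 and 8). The falls still prevailed for elongation (7 higher, 15 lower), p53 targets (7 and 10), 3' end processing (9 and 10) and Hippo targets (4 and 5). Ribosomal proteins had a median of -0.03 as deposited (adjusted p 1.56e-09; adjusted p = 0.914 with an estimated correlation) and 0.76 relative to the array medians, where 66 of 68 rose (adjusted p 1.96e-20; 0.451 with an estimated correlation). Oxidative phosphorylation subunits had -0.06 (adjusted p 1.03e-08; 0.914 with an estimated correlation) and 0.73, where 65 of 69 rose (adjusted p 3.76e-13; 0.542 with an estimated correlation).

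Lines shared much of the 500 nM response. Of the 96 genes higher in each line, 69 were higher in both, against 1 if the lines were independent, and 6097 were lower in both, against 5272. Relative to the array medians 2579 were higher in both (1256 if independent) and 2401 lower in both (851 if independent). Across genes the effects correlated with r = 0.883 and rho = 0.847. Averaged over both lines, which sets 4 arrays against 4, 8786 genes were lower and 114 higher as deposited, and 3338 lower and 4558 (57.7%) higher relative to the array medians.

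At 100 nM, A673 cells had their largest fitted fall in INTS6 and their largest fitted rise in SEC24A. INTS6, an Integrator subunit gene, fell by 3.33 ± 0.21 (SE, n = 2 against 2), 10.0-fold lower as deposited and -2.71 relative to the array medians. FBXO28 (-2.85), an F-box gene, KAT14 (-2.84), an acetyltransferase complex gene, HERC4 (-2.83), a ubiquitin ligase gene with a 100 nM mean of 5.86, and ZC3H4 (-2.72) followed. SEC24A, a gene of COPII vesicle coats, rose by 2.54 ± 0.21, 5.82-fold as deposited and 3.16 in relative terms, ahead of the chromatin regulator gene PHF12 (2.18). SNORA65 (2.19), the ESCRT gene MVB12B (2.17) and EID3 (2.06) started under 5.95 with DMSO. BRCA1 fell by 1.81 (relative -1.19), FLI1 fell by 1.44 (relative -0.82) and CDK13 fell by 1.42 (relative -0.80), while CCNK (-0.21), EWSR1 (-0.22) and MYC (-0.06) had adjusted p-values of 0.344, 0.287 and 0.769 and turn positive in relative terms (0.41, 0.40 and 0.57, adjusted p 0.00542, 0.00572 and 0.000357). CDK12 was at -0.46 (adjusted p 0.048) and 0.17 relative to the array medians (adjusted p 0.289), and its as-deposited call ended without 10 of the 12 arrays in turn. Its adjusted p was 0.292 and 0.0652 without A673 DMSO replicates 1 and 2, 0.309 and 0.0819 without the 100 nM replicates, 0.070 and 0.0697 without TC32 DMSO replicates, 0.0693 and 0.0698 without TC32 100 nM replicates, and 0.0679 and 0.0682 without TC32 500 nM replicates. By limma 5955 genes were lower and 134 higher as deposited. Centring took a shift of -0.621 out of the comparison, after which 1724 were lower and 2507 (59.3%) higher, against 2.2% higher as deposited. All 14 of the 17 named genes that passed had both 100 nM arrays beyond both DMSO arrays.

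The total of 6089 for A673 at 100 nM dropped to 3245 without replicate 1 of its DMSO arrays, 4041 without replicate 1 and 3421 without replicate 2 of its 100 nM arrays. The higher genes numbered 89, 87 and 76 without these, and 228 without either 500 nM array. In the DNA damage response list 29 of 33 genes were lower at 100 nM (camera adjusted p 0.000198; adjusted p = 0.927 with an estimated correlation). Among histones 7 of 26 rose and 3 fell (adjusted p 9.83e-09; adjusted p = 0.927 with an estimated correlation), and 4 rose without replicate 1 of the 100 nM arrays. The falls were 1 without replicate 1 of the DMSO arrays or replicate 2 of the 100 nM arrays, 6 without DMSO replicate 2 and 7 without either 500 nM array. Among immediate-early transcripts 6 of 35 rose and 7 fell (adjusted p 6.60e-11; adjusted p = 0.927 with an estimated correlation), or 11 and 10 without either 500 nM array. Without replicate 1 of the DMSO arrays 1 fell, and without replicates 1 and 2 of the 100 nM arrays 3 and 2 did. In relative terms 19 histones and 26 immediate-early transcripts were higher. G2/M genes fell in 20 of 28 cases as deposited without passing the list test (camera adjusted p 0.121), a result that turned without either 500 nM array.

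In TC32 at 100 nM the median change was -0.07 as deposited, and SEC24A again had the highest fitted rise. It rose by 3.24 ± 0.21 (SE, n = 2 against 2), at least 7.53-fold as deposited from a DMSO mean of 5.62, and 3.44 relative to the array medians. The cytoplasmic polyadenylation gene CPEB2 (2.94) and the oncostatin M receptor gene OSMR (2.71) rose from DMSO means above 5.95, and MVB12B (2.98) and the chromatin remodeller gene CHD2 (2.84) from means of 4.53 and 5.83 under it. ZC3H4 fell by 3.10 (relative -2.90), and PRR5L (-2.97) and the gamma-tubulin complex gene TUBGCP3 (-2.85) also fell. The kinase gene SIK2 (-2.98) and the transporter gene ABCA10 (-2.96) had 100 nM means under 5.95. FLI1 fell by 2.72 (relative -2.51) and BRCA1 fell by 1.84 (relative -1.64). CDK12 (0.34), CDK13 (-0.29), CCNK (0.12), EWSR1 (0.20) and MYC (0.38) had adjusted p-values of 0.255, 0.365, 0.766, 0.52 and 0.0973 as deposited. After centring CDK12 (0.54, adjusted p 0.00091), CCNK (0.33, 0.0185), EWSR1 (0.41, 0.00421) and MYC (0.58, 0.000194) passed the test as higher, and CDK13 (-0.08, 0.697) did not pass. By limma 2127 genes were lower and 564 (21%) higher as deposited. Centring took a shift of -0.205 out of the comparison, after which 2154 were lower and 3106 (59%) higher. All 12 of the 17 named genes that passed had both 100 nM arrays beyond both DMSO arrays, which the naming rule required of the 5 rises and 5 falls.

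The total of 2691 for TC32 at 100 nM was 1584 without replicate 1 of its DMSO arrays, 1665 without replicate 1 of its 100 nM arrays and 4540 without either A673 500 nM array. The higher genes numbered 350 and 248 without DMSO replicates 1 and 2, 267 and 323 without the 100 nM replicates, and 1291 and 1290 without the A673 500 nM replicates. In the DNA damage response list 17 of 33 genes fell (19 adjusted over the list alone; camera adjusted p 0.00154; adjusted p = 0.893 with an estimated correlation). Immediate-early transcripts rose in 13 of 35 cases (14 adjusted over the list alone; adjusted p 3.39e-08; adjusted p = 0.893 with an estimated correlation), or 7 without replicate 2 of the DMSO arrays, 8 without either 100 nM array and 21 without either A673 500 nM array. Histones rose in 10 of 26 cases (11 adjusted over the list alone; adjusted p 9.57e-06; adjusted p = 0.893 with an estimated correlation), or 5 without replicate 1 of the 100 nM arrays and 6 without either DMSO array. Across genes the 100 nM effects of the lines correlated with r = 0.857 and rho = 0.792, and 123 of the 134 genes higher in A673 were higher in TC32, against 7 if independent.

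**Figure D3:**
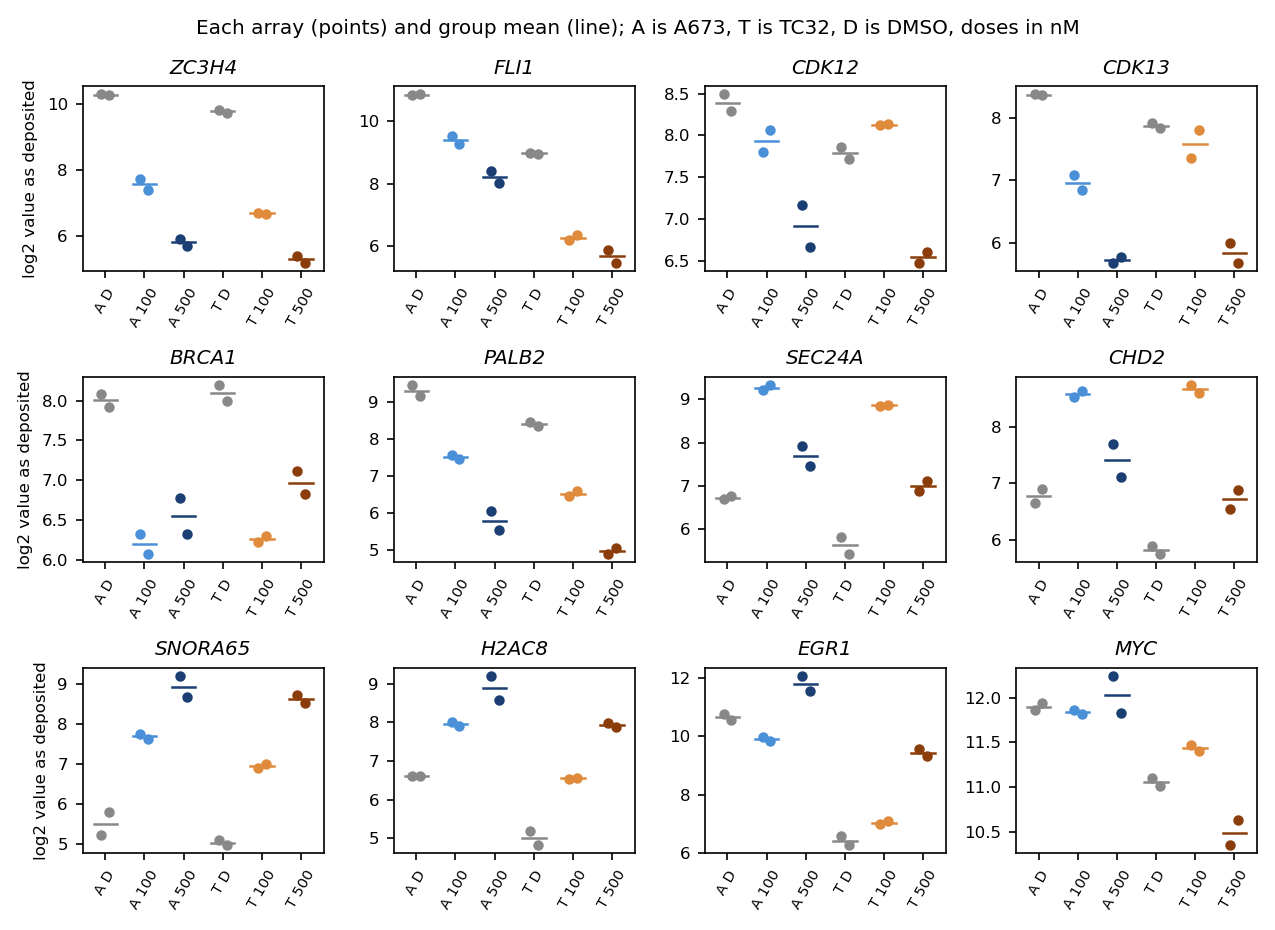
Deposited log2 value of 12 named genes on each array (points) with the group mean (line), in A673 (A) and TC32 (T) with DMSO (D) and at 100 nM and 500 nM. ZC3H4 fell from 10.29 with DMSO to 5.80 at 500 nM in A673, and SEC24A went from 5.62 with DMSO to 8.86 at 100 nM in TC32, directions that hold relative to the array medians, whereas MYC turns from -0.57 to 0.23 in TC32 at 500 nM.

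Genes of transcription elongation and mitosis were lower, and histones higher, at 500 nM than at 100 nM in both lines. In A673, 20 of 31 elongation genes fell between the doses (22 adjusted over the list alone; camera adjusted p 0.000366), 18 of 28 G2/M genes fell (21 adjusted over the list alone; adjusted p 0.000142) and 10 of 26 histones rose (11 adjusted over the list alone; adjusted p 2.59e-09), with adjusted p = 0.973 for each with an estimated correlation. The elongation falls were 12 and 13 without replicates 1 and 2 of the 100 nM arrays, and 6 histones rose and 6 fell without replicate 1 of the 500 nM arrays. In TC32, 28 elongation genes fell (adjusted p 0.000114), 24 G2/M genes fell (adjusted p 0.00507) and 15 histones rose while 7 fell (adjusted p 5.46e-12), with adjusted p = 0.88 for each with an estimated correlation. Only 3 histones fell without replicate 1 of the 100 nM arrays or replicate 2 of the 500 nM arrays. At 100 nM in TC32 the elongation list had lain above other genes, with a median of 0.19, 7 genes risen and 4 fallen (adjusted p 0.0169; adjusted p = 0.893 with an estimated correlation). The rises and falls were 13 and 7 without either A673 500 nM array, 4 and 3 without replicate 1 and 5 and 2 without replicate 2 of the TC32 100 nM arrays, and 5 and 2 without DMSO replicate 1. CDK12 and CDK13 belong to that list, with group means of 8.13 and 7.59 at 100 nM against 6.54 and 5.83 at 500 nM in TC32. Ribosome biogenesis genes (24 of 29 fell; adjusted p 0.000154), transcription factors of Ewing sarcoma (17 of 20 fell; 0.00813) and Wnt, TGF-beta and Hippo targets (11 of 12 fell; 0.0071) were also lower at 500 nM than at 100 nM in TC32, each with adjusted p = 0.88 with an estimated correlation. Of those transcription factors 11 fell without replicate 2 of the 100 nM arrays.

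As deposited, 2706 genes were lower and 91 (3.3%) higher at 500 nM than at 100 nM in A673. Centring took a shift of -0.214 out of the comparison, after which 2555 were lower and 1067 (29.5%) higher. In TC32 the counts were 5632 lower and 112 (1.9%) higher. Centring took out a shift of -0.590 there, after which they were 3017 lower and 2978 (49.7%) higher. The A673 total of 2797 was 6638 without replicate 1 of the 500 nM arrays and 1783 without replicate 1 of the 100 nM arrays. The count of higher genes in A673 was 57 and 953 without replicates 1 and 2 of the 500 nM arrays and 50 and 43 without those of the 100 nM arrays. In TC32 it was 61 without replicate 1 of its 100 nM arrays, 65 and 66 without its 500 nM replicates, and 213 and 214 without the A673 500 nM replicates. Doses within a line correlated less across genes than lines did at either dose, with r = 0.673 in A673 and r = 0.548 in TC32. Unchanged groups that share their DMSO arrays gave 0.501 and 0.499 in simulations, and the covariance beyond that was 0.185 and 0.219.

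**Figure D4:**
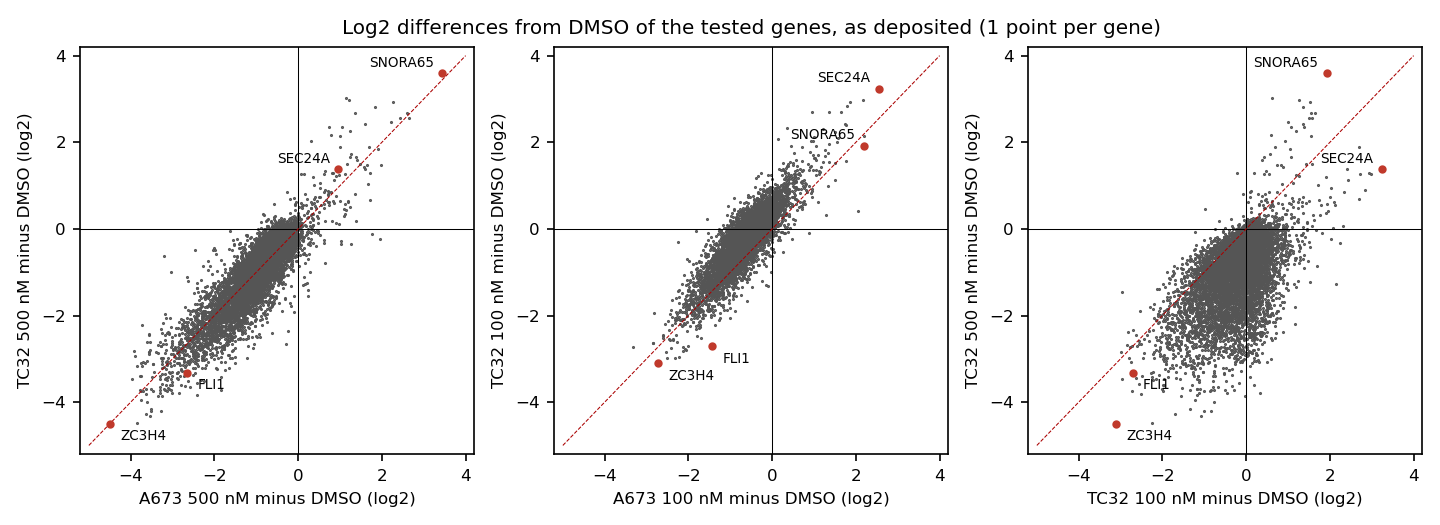
Log2 difference from DMSO of each tested gene as deposited, for A673 against TC32 at 500 nM (left), the same at 100 nM (middle) and TC32 at 100 nM against 500 nM (right), with the line of equality dashed. The correlations across genes were 0.883, 0.857 and 0.548, and SEC24A lay at 3.24 at 100 nM in TC32.

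The 500 nM effect differed between lines in 186 genes by limma, 56 with a higher and 130 with a lower TC32 effect. The genes with the largest differences included developmental regulators expressed mainly in 1 of the lines. LIN28B, a gene of an RNA-binding protein that blocks let-7 maturation, fell from 10.53 to 7.33 in A673 and had group means of 4.49 and 3.86 in TC32, a difference of effects of 2.58 ± 0.30 (SE). The homeobox gene OTX2 and the receptor gene ROR2 had differences of 2.03 and 1.98 of the same kind, and the regulators OSR2 and TBX5, expressed mainly in TC32, had -2.36 and -2.10. In the line with the smaller change these 5 genes lay under the minimum level of the brightness filter (5.95) with DMSO, where a gene has little room to fall, so the differences do not show an unequal response. FOS had a group mean of 11.60 at 500 nM against 9.84 with DMSO in A673 and 10.54 against 10.66 in TC32 (difference -1.88), and EGR1 had a larger effect in TC32 (1.88). PLK2 had a fitted difference of 1.76, but its DMSO mean in TC32 (4.73) lay under 5.95, and counted from that level it rose by 1.76 in TC32 against 1.22 in A673. EID3 (-2.18), at 5.83 with DMSO in A673, and the DNA glycosylase gene TDG (-1.89) had lower effects in TC32.

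Relative to the array medians 1002 genes differed at 500 nM, 313 higher and 689 lower in TC32. Centring took a shift of 0.04 out of that comparison. The as-deposited total was 62 and 94 without replicates 1 and 2 of the TC32 500 nM arrays, 66 and 94 without those of TC32 with DMSO, 106 and 113 without those of A673 with DMSO, and 3370 and 1649 without those of A673 at 500 nM. At 100 nM 227 genes (96.2%) had a higher and 9 a lower TC32 effect as deposited. Centring took a shift of 0.416 out of the comparison, after which 88 (32.2%) were higher and 185 lower. The 100 nM total of 236 was 8 and 544 without replicates 1 and 2 of the A673 DMSO arrays, 17 and 11 without those of A673 at 100 nM, 5020 and 5022 without those of A673 at 500 nM, 37 and 13 without those of TC32 with DMSO, 13 and 54 without those of TC32 at 100 nM, and 85 without either TC32 500 nM array.

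Under DMSO the lines differed widely, A673 having the higher array medians. The collagenase gene MMP1 had a group mean of 13.52 in A673 and 4.27 in TC32. Where the lower line lay under the brightness minimum of 5.95, as for all genes named here but PRRX1, the fold was counted from that level (n = 2 against 2). MMP1 was thus at least 190-fold higher in A673, the aldo-keto reductase gene AKR1C3 at least 106-fold, the chromatin architecture gene HMGA2 at least 72.3-fold, the keratin gene KRT18 at least 64.0-fold and the cell adhesion gene NRCAM at least 13.6-fold. In TC32 MGP, an inhibitor of calcification, was at least 45.2-fold higher, the small heat shock gene HSPB8 at least 23.3-fold, the BMP antagonist gene CHRDL1 at least 13.7-fold and the proteoglycan gene SRGN at least 13.5-fold, and the homeobox gene PRRX1 was 31.8-fold higher. All these folds are as deposited, and centring lowers those in favour of A673 and raises those in favour of TC32. By limma 7854 genes (93.8%) were higher and 520 lower in A673 as deposited. Centring took a shift of 0.694 out of the comparison, after which 3419 (60.9%) were higher and 2192 lower. Epithelial markers, 4 of 4 of them higher, lay above other genes in A673 (camera adjusted p 0.00687; adjusted p = 0.977 with an estimated correlation). That call ended after centring (adjusted p 0.283) and without replicate 1 or replicate 2 of the A673 500 nM arrays (0.436 and 0.437), and 2 of the 4 were higher without replicate 1 of the A673 DMSO arrays.

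CDK12 and CDK13 act during elongation, which raises the question of whether changes follow gene length. Across 10145 genes the 500 nM effect was lower in longer genes, with Spearman's rho of -0.227 in A673 and -0.115 in TC32, and rho was -0.094 and -0.037 at 100 nM. The 500 nM values depend on brightness and scaling, since within the genes of middle brightness rho was -0.138 in A673 and 0 in TC32, and after quantile normalization -0.154 and -0.044. In A673 at 500 nM the median change as deposited went from -0.55 in the shortest quintile (median length 4.67 kb) to -0.89 in the fourth (55.7 kb) and -0.85 in the longest (143 kb), and relative to the array medians from 0.29 to -0.01. In TC32 at 500 nM the medians were -0.44, -0.80 and -0.67 in the same quintiles. The baseline difference between lines had a rho of 0.033 with length. Leaving out replicate 2 of the A673 DMSO arrays moved rho for A673 at 100 nM to -0.04, leaving out replicate 1 moved it to -0.144. Leaving out replicate 1 of the TC32 100 nM arrays moved rho for TC32 at 100 nM to -0.013 and replicate 2 to -0.056.

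**Figure D5:**
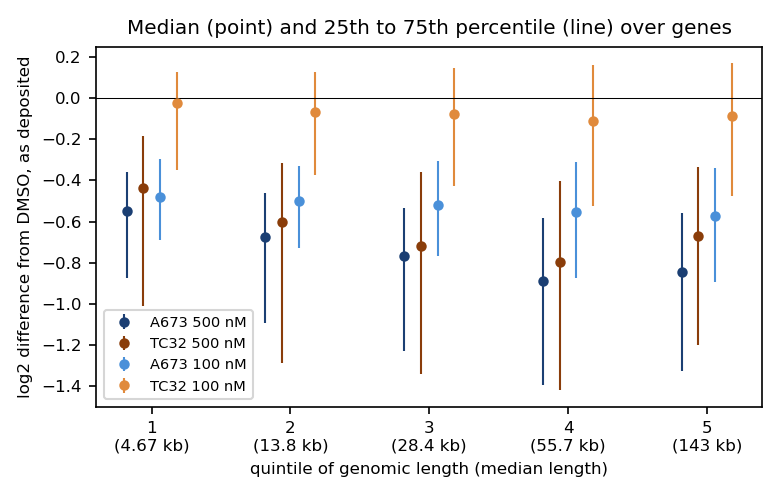
Median (point) and 25th to 75th percentile (line) of the log2 difference from DMSO as deposited over the genes of each quintile of genomic length, for both doses in A673 and TC32. Medians at 500 nM fell from -0.55 in the shortest to -0.89 in the fourth quintile in A673 and from -0.44 to -0.80 in TC32, while relative to the array medians the shortest quintile of A673 lay at 0.29.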

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

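Except for the count over other splits of the arrays, the tests weighed in this part were chosen only after the results had been seen.

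The effect of 500 nM THZ531 differed between the lines in 186 genes and that of 100 nM in 236 genes by limma's test of the difference itself, as deposited. Both counts depended on the processing and on single arrays. They were 1002 and 273 after centring and 2212 and 695 after quantile normalization. The 500 nM count was 106 and 113 without A673 DMSO replicate 1 or 2, 3370 and 1649 without A673 500 nM replicate 1 or 2, 66 and 94 without TC32 DMSO replicate 1 or 2, and 62 and 94 without TC32 500 nM replicate 1 or 2. The 100 nM count was 8 and 544 without A673 DMSO replicate 1 or 2, 17 and 11 without A673 100 nM replicate 1 or 2, and 5020 and 5022 without A673 500 nM replicate 1 or 2. It was 37 and 13 without TC32 DMSO replicate 1 or 2, 13 and 54 without TC32 100 nM replicate 1 or 2, and 85 without either TC32 500 nM array.

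At 500 nM the effect in TC32 was below that in A673 for OSR2 (-2.36), EID3 (-2.18), TBX5 (-2.10), TDG (-1.89) and FOS (-1.88). It was above it for LIN28B (2.58), OTX2 (2.03), ROR2 (1.98), EGR1 (1.88) and PLK2 (1.76). These 10 differences kept their direction and their side of the threshold under each alternative that tested them, leaving out each array included. With the filter at the 60th percentile OSR2, TBX5, LIN28B, OTX2, ROR2 and PLK2 were not tested, and fitting each line alone gives no such difference. LIN28B, OTX2 and ROR2 in TC32 and OSR2 and TBX5 in A673 lay under the brightness minimum of 5.95 with DMSO, where a gene has little room to fall, so these 5 differences do not show an unequal response to the compound. PLK2 in TC32 (4.73) and EID3 in A673 (5.83) also started under that level, so their fitted values are not taken as the size of the difference. Counted from it, PLK2 rose by 1.76 in TC32 against 1.22 in A673. EID3 rose by 1.84 in A673 counted in this way, while its TC32 mean was 7.25 with DMSO and 7.03 at 500 nM.

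At 100 nM the effect in TC32 was above that in A673 for CDK13 (1.13, adjusted p 0.0182) and below it for FLI1 (-1.27, adjusted p 0.00617). After centring CDK13 was no longer past the threshold (0.71, adjusted p 0.130), nor after quantile normalization (0.65, adjusted p 0.169), while FLI1 was (-1.69 and -1.53). The CDK13 call ended without A673 DMSO replicate 1 (adjusted p 0.164), either A673 100 nM array (0.101 and 0.287), either TC32 DMSO array (0.102 and 0.267) or either TC32 100 nM array (0.0739 and 0.189). The FLI1 call ended without A673 DMSO replicate 1 (0.129), either A673 100 nM array (0.150 and 0.0728), either TC32 DMSO array (0.0691 and 0.121) or TC32 100 nM replicate 1 (0.169).

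Gene lists also differed between the lines by camera, with the median difference relative to the array medians given beside each adjusted p. At 500 nM the TC32 effect lay lower for transcription factors of Ewing sarcoma (-0.21, adjusted p 0.000596), immediate-early transcripts (-0.22, 0.00445) and G1/S and DNA replication (-0.06, 0.0331). It also lay lower for ribosome biogenesis (-0.27, 3.01e-05) and Wnt, TGF-beta and Hippo targets (-0.62, 3.88e-07). It lay higher for p53 targets (0.06, 0.0257), replication-dependent histones (0.34, 2.86e-05), cytoplasmic ribosomal proteins (0.22, 3.88e-07) and oxidative phosphorylation subunits (0.29, 8.15e-07). At 100 nM it lay higher for p53 targets (0.25, 0.00121) and lower for G1/S and DNA replication (-0.13, 0.0253). After centring, the calls at 500 nM ended for p53 targets (adjusted p 0.113) and G1/S (0.099). With an estimated correlation the adjusted p was 0.976 for each list at 500 nM and 0.979 for each at 100 nM.

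Single arrays carried some of these calls. The p53 call at 500 nM ended without A673 DMSO replicate 2 (adjusted p 0.0767), A673 500 nM replicate 1 (0.422), TC32 DMSO replicate 1 (0.072) or TC32 500 nM replicate 2 (0.0883). The G1/S call at 500 nM ended without A673 DMSO replicate 1 (0.0862), A673 500 nM replicate 1 (0.533) or TC32 DMSO replicate 1 (0.072). The G1/S call at 100 nM ended without A673 DMSO replicate 1 (0.0529), A673 100 nM replicate 2 (0.0968), either A673 500 nM array (0.124), TC32 DMSO replicate 1 (0.0846) or TC32 100 nM replicate 1 (0.105).

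Most genes were below DMSO at 500 nM as deposited. By limma the real split of the arrays gave 8329 genes over both lines (8466 at an unadjusted p under 0.05), and the highest of the others gave 0 (5506). Only the real split, 1 of 34, reached that count. Every other split put both 500 nM and DMSO arrays on each side, so any difference between these entered the spread and lowered its count. Some of the other splits were also unbalanced within the lines, unlike the real one. For these reasons, and because 34 splits are too few, chance is not excluded. Offsets of single arrays unrelated to treatment are argued against in TC32, whose replicates differ by a median of at most 0.121 against a median change of -0.64, but cannot be told apart from a real fall in A673, whose 500 nM replicates differ by 0.523. A factor for each array, equal for every gene, would shift all genes alike. As the only cause it is argued against by the calls after centring given below. Over the kept genes in deciles of mean signal, the median change at 500 nM was -0.133, -0.952 and -0.523 in deciles 1, 7 and 10 in A673. In TC32 it was -0.127, -0.939 and -0.325. Dim genes have little room to fall, but decile 10 is the brightest. The difference between A673 and TC32 under DMSO, with no compound, also varied, at 0.201, 0.883 and 0.738 in those deciles. The deciles alone therefore do not separate a factor for each array from unequal changes. As part of the fall, a factor for each array cannot be told apart from a real change in either line. Arrays of a dose may share one, and centring fixes the balance around the median. After centring, 33.1% of the genes lower in A673 and 48.7% of those lower in TC32 were still lower, while 1287 and 504 of them were higher, which shows unequal changes on top of any common shift. A fall that deepens with the dose may contribute, since the array medians went down at each dose step in both lines, with -0.291 as the smallest step against a pooled SD of 0.166 between replicates, although the median of the changes gene by gene was only -0.07 in TC32 at 100 nM.

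The entries with at most 2 decimals, which no comparison used, hold a signal arranged differently from the rest. In 965 bright entries of this kind, 0 of 12 columns lay nearest to their own replicate, against 12 of 12 in the 3-decimal entries, which argues against the same array order under another normalization. A candidate explanation is a column order shifted by an odd number of places, since all 12 columns paired as replicates moved by 1 place would, the last column with the first. By how many places is open, because the correlation with the 3-decimal values of the same genes (56 entries of 40 genes) was 0.114 as labelled, 0.249 for a shift by 1 place and 0.219 for the same shift the other way. No biological explanation was tested.

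Effects of the 2 doses within a line correlated less than effects of the 2 lines at the same dose. Noise in the smaller 100 nM effects is argued against by the correlation of 0.857 between the lines at 100 nM, above the 0.673 and 0.548 between doses. The dose itself may shape how strongly genes respond, since the 159 genes at least 2-fold higher at 100 nM in A673, in relative terms, had a median difference of -0.43 between 500 nM and 100 nM in TC32, below the 2.5th percentile of lists matched on brightness (-0.04). As a set they nonetheless stayed above DMSO in TC32 at 500 nM in relative terms, with a median of 0.94 against 0.10 for the matched lists. Centring had taken a shift of -0.795 out of that comparison, and a median does not show that each gene responds at both doses. As deposited, of the 564 genes higher at 100 nM in TC32, 241 were lower than DMSO at 500 nM and 74 higher. Arrays of a dose processed together in both lines would give the same pattern, and the labels name no batch, so that explanation stays open.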

How the results depend on the processing

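Of the alternatives, putting back the entries with at most 2 decimals and a replicate block with the TC32 DMSO numbers crossed were chosen after seeing the data, and the others before. Centring on the external RNA controls was not run, since their probe sets were not used here, nor were another pseudocount, since the values are on a log2 scale, and transcript length in place of genomic length, which was not analysed here. Where no reason is given, the cause was not tested.

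Over the alternatives and the arrays left out, 179 of the counts of changed genes stayed within 1.5 times the value reported and 67 did not. For named genes 4427 comparisons kept their direction and side of the threshold, 110 lost the threshold, 31 gained it and 56 changed sign. Averaging the probe sets of a gene, and a robust variance trend, moved none of the counts by more than 1.5 times. For averaging that was near certain, since only 21 kept genes had more than 1 distinct set of values. Its unchanged comparisons stand in the totals above.

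Centring each array sets its median to that of the others, so the median change went from negative to 0.10, 0.10 and 0.15 for A673 500 nM, A673 100 nM and TC32 500 nM, and to 0.13 for TC32 100 nM. The count rose to 5260 for TC32 100 nM and to 1002 for the difference between lines at 500 nM. Estimates negative as deposited and positive after centring, whether or not they passed the test, were at 100 nM in A673 those of CCNK (0.41), CDK12 (0.17), EWSR1 (0.40) and MYC (0.57). At 500 nM in A673 they were those of CD79A (0.40), CLDN4 (0.46), EWSR1 (0.38), HBB (0.43), MUC1 (0.53), RPL39L (0.038), SDHA (0.039), SNAP25 (0.23), SYP (0.29) and VWF (0.24). At 500 nM in TC32 they were those of CD79A (0.51), CLDN4 (0.49), EWSR1 (0.38), H1-3 (0.28), HBB (0.44), MUC1 (0.46), MYC (0.23), RPL39L (0.12), SYP (0.25), THY1 (0.13) and TUBB3 (0.41).

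Quantile normalization gives the arrays equal distributions, so the median change became 0.12, 0.038 and 0.15 for A673 500 nM, A673 100 nM and TC32 500 nM. Counts were 4028 for A673 100 nM, 5102 for A673 500 nM against 100 nM, 5427 for TC32 100 nM, and 2212 and 695 for the difference between lines at 500 and 100 nM. The correlation with length went to -0.154 in A673 and -0.044 in TC32 at 500 nM. Estimates turned positive, again whether or not they passed, at 100 nM in A673 for CCNK (0.39), CDK12 (0.24), EWSR1 (0.16) and MYC (0.25). At 500 nM in A673 they did so for CCNK (0.11), CD79A (0.53), CLDN4 (0.64), EWSR1 (0.16), FOXO1 (0.015), H1-3 (0.01), HBB (0.48), MUC1 (0.72), PDGFRB (0.23), RPL39L (0.11), SNAP25 (0.42), SPRY1 (0.10), SYP (0.54) and VWF (0.12). At 500 nM in TC32 they did so for CCNK (0.089), CD79A (0.79), CLDN4 (0.80), COL3A1 (0.058), EWSR1 (0.17), H1-3 (0.60), H1-4 (0.31), HBB (0.46), MUC1 (0.81), RPL39L (0.013), SYP (0.57), THY1 (0.34) and TUBB3 (0.009).

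With the filter at the 60th percentile fewer genes were tested (6766), and counts were 4018 for A673 100 nM, 1786 for TC32 100 nM and 108 and 132 for the difference between lines at 500 and 100 nM. The correlation between doses in TC32 was 0.492. Without a filter 14 lists were past the threshold for A673 500 nM and 16 for TC32 500 nM, the median change was -0.53 and -0.40, and the lines correlated by 0.771 at 100 nM. With the 2-decimal entries put back, the difference between lines at 500 nM held 365 genes and the lines correlated by 0.822 at 500 nM.

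Counting each probe set instead of each gene raises the counts by construction. They were 22589 and 15573 for A673 500 and 100 nM, 7884 between these doses, 17213 and 7147 for TC32, 15235 between its doses, and 23165 over both lines. For the difference between lines they were 430 and 746, and under DMSO 21473. Asking for a fold change of 2 or more lowers counts by construction, to 3429, 1548 and 1068 in A673, 3466, 969 and 2625 in TC32, 3428 over both lines and 3639 under DMSO.

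With each line fitted alone, counts were 3431 for A673 100 nM, 1774 for A673 500 nM against 100 nM and 4795 for TC32 100 nM. Without the intensity trend 367 genes differed between lines at 100 nM. Camera with an estimated correlation called 0 lists in each of A673 500 nM, A673 100 nM, TC32 500 nM and TC32 100 nM, and at an unadjusted p under 0.05 it called 0, 0, 1 and 0 of the 24.

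The replicate numbers within a line were entered as a block, although nothing in the labels shows that they pair arrays across doses. With the block 310 and 956 genes differed between lines at 500 and 100 nM, and with the TC32 DMSO pairing crossed 314 and 1000, so the rise does not rest on that pairing.

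Within the bright genes the correlation with length was -0.157 for TC32 500 nM and 0.022 for TC32 100 nM, a change of sign. Within the middle genes it was -0.138 for A673 500 nM, 0 for TC32 500 nM and 0.015 for TC32 100 nM, the last also a change of sign. Within the dim genes it was -0.093 for TC32 100 nM.

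Leaving out 1 array leaves 1 sample in its group, which is assumed to vary like the other groups. Counts ran from 6004 to 9755 for A673 500 nM, from 3245 (without A673 DMSO replicate 1) to 8264 (without A673 500 nM replicate 2) for A673 100 nM, and from 1783 (without A673 100 nM replicate 1) to 6638 (without A673 500 nM replicate 1) between these doses. In TC32 they ran from 5048 to 7806 at 500 nM, from 1584 (without DMSO replicate 1) to 4540 (without A673 500 nM replicate 1) at 100 nM, and from 4297 to 7216 between doses. Over both lines they ran from 7735 to 9874, and under DMSO from 6932 to 9110. For the difference between lines they ran from 62 (without TC32 500 nM replicate 1) to 3370 (without A673 500 nM replicate 1) at 500 nM, and from 8 (without A673 DMSO replicate 1) to 5022 (without A673 500 nM replicate 2) at 100 nM. The median change in A673 at 500 nM ran from -1.01 (without replicate 1) to -0.47 (without replicate 2). Lists past the threshold ran from 7 to 11 for A673 500 nM. The lines correlated by 0.857 to 0.883 at 500 nM and by 0.791 to 0.866 at 100 nM.

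Signal over background limits which genes can be read. No detection calls were used here, so the filter at the 40th percentile stands in for background. A gene near it has little room to fall, so its fold change can come out too small.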

Other observations

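The tests in this part were chosen only after the result was seen, except that on the length of genes higher at 500 nM, and the gene groups were picked by symbol after the data had been examined.

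Genes of small nucleolar RNAs, which guide modification of ribosomal and spliceosomal RNA, were among the few genes above DMSO at 500 nM. Of 19 tested, 9 rose and 1 fell in A673 and 7 rose and 2 fell in TC32 as deposited. After centring 18 and 17 rose, and after quantile normalization 17 and 15. SNORA65 rose most in both lines (3.44 and 3.60). SNORD12B, SNORA84 and SNORA74A had the next highest fitted values, in an order that differed between the lines. SNORA74B in A673 (-0.54) and SNORA30 in TC32 (-0.57) fell as deposited and turned positive after centring (0.29 and 0.22). At 100 nM 6 rose and 3 fell in A673 and 9 rose in TC32. Since the leading members drew attention to the group, the test left out those that the naming rule had picked. It took genes of any brightness and matched on the DMSO level of the line and on length. The 40 others had a median relative change at 500 nM of 0.814 in A673 and 0.83 in TC32, over the values that 2.5% of matched lists exceed (0.59 and 0.64). Centring took out shifts of about that size (-0.835 and -0.795), so as deposited the 40 changed little. The matched lists, with relative medians of 0.50 and 0.56, lay below DMSO as deposited. For these 40 the test therefore shows a change above that of the matched lists, not a rise over DMSO as deposited. Length was matched in 5 bins only, so a difference in length within a bin may contribute. The gene-level values do not tell mature small nucleolar RNAs from longer transcripts of the same genes. Why the leading genes rise was not tested.

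Of 8 host genes of small nucleolar RNAs 2 rose and 4 fell in A673 at 500 nM as deposited, and 2 rose and 5 fell in TC32, while relative to the array medians 6 and 4 rose and 2 fell in each line. SNHG17 (1.92 and 1.85) and SNHG9 (0.99 and 1.24) rose, and SNHG12 (-1.14 and -2.15) and SNHG7 (-1.53 and -2.05) fell on either scale.

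Genes of the ZNF family, most of them zinc finger transcription factors, moved the other way. Of 245 tested, 228 fell and 1 rose in A673 at 500 nM as deposited, and 219 fell and 1 rose in TC32. After centring 163 and 177 fell and 20 and 27 rose, and after quantile normalization 160 and 177 fell. ZNF7 (-3.53 and -4.33) fell deeply in both lines, and ZNF33A (0.74 and 0.62) was the riser in both. In the same kind of test the 459 members not picked by the naming rule had a median relative change of -0.357 in A673 and -0.48 in TC32 at 500 nM, under the 2.5th percentile of matched lists (0.28 and 0.32). At 100 nM the 245 tested genes, named members included, had relative medians of -0.167 in A673 and -0.155 in TC32. Lists matched on brightness and length had 2.5th percentiles of 0.033 and 0.0675 there. As deposited 183 and 97 fell and 1 and 11 rose at that dose. A change below that of the matched lists was thus not particular to 500 nM, in a group picked after the same data had been examined.

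Gene length gave 1 positive and 1 negative result. The 100 genes at least 2-fold higher at 500 nM in both lines, relative to the array medians, had a median genomic length of 4.22 kb. With histones, small nucleolar RNAs and immediate-early genes left out, the other 66 had 12.2 kb, under the 2.5th percentile of lists matched on brightness (18.2 kb). Short length may thus go with a rise at 500 nM beyond those groups. That genes higher at 100 nM are set apart by long length was not borne out. The 118 genes higher in both lines had a median of 58.1 kb, but the 247 genes lower in both lines were long too, at 48.0 kb, where 2.5% of matched lists exceed 37.03 kb.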
